A study of Caenorhabditis elegans with 4 samples.

How the data were processed

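Whole N2 worms at the L3 larval stage were ground after freezing, fixed with 1% formaldehyde over 10 minutes, and sheared by 14 sonication pulses lasting 30 seconds each, per the labels' protocols. Material recovered with the HTZ-1 antibody (2 libraries) and input DNA (2 libraries) was sequenced on Illumina instruments. BWA is named in the submitters' processing notes, with no version. The authors deposited 2 peak lists in GFF3 format on WormBase WS220, per the file headers. Comment lines of a coordinate liftover step name 39 peaks of the larger list and 27 of the smaller list whose internal structure changed. The build the coordinates were lifted from is not given in the sources used here. The source field reads MA2C while the peak names begin with MACS, per the files, so the caller is not certain from them. The caller's settings, the use of input, and whether replicates were pooled are stated by no header or label. The name given to the larger list carries a term that reads as a version of MACS, and that of the smaller list a term that reads as joined data. Neither term is explained, so neither was used as a fact, and a different caller or pooling of reads stays possible behind every difference between the lists.

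The deposited score of each peak has no stated scale. Values ran from 50.1 to 3233 in the larger list and from 50.02 to 3223 in the smaller list, with 569 and 81 peaks at exactly 3100. Ranks above that value therefore carry little weight. The score was therefore used only to rank, filter and describe peaks within a list, and to correlate ranks between lists. The other deposited values were the start and end of each peak. In the smaller list 5 peaks at the beginning of chromosomes had no start and were given position 1 for overlaps and left out of width statistics. The single mitochondrial peak was left out of every test. Peaks within a list did not overlap each other. No sample columns were left unused, since neither file holds values per library.

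Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Chromosome lengths of WS220 were not used here. Each chromosome was taken to run from base 1 to the last peak end in either list, 100.1 Mb in all and 82.4 Mb on autosomes. Overlap needed at least 1 bp. Random placement shuffled the peak widths of a list on each chromosome and drew new positions evenly at random, without overlap, 1000 times with a fixed seed. The empirical p counts placements at least as high as observed. Densities of X against autosomes and of centres against arms were compared by exact binomial tests, two-sided, against the share of length, with exact (Clopper-Pearson) intervals turned into ratios. They take peaks as independent, so with clustered peaks their p-values are too small and their intervals too narrow. A gap was the distance between the end of a peak and the start of the next. Correlations across peaks or windows carry percentile intervals from 1000 bootstrap draws. Shares have 95% Wilson intervals unless stated. The functions were tested on simulated peaks: a planted sharing of 60% over 4940 simulated peaks came back as 59.7%, a planted X to autosome ratio of 0.5 over 5474 simulated peaks as 0.500, and a planted stratified difference of -20 percentage points over 4000 simulated peaks as -18.0.

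The design, the alternatives and the rule for named sites were fixed before the data were examined. The rule names the 10 highest-scoring peaks of each list by position, and was kept although many peaks share a score of 3100. Ties were to be broken by fold enrichment and then by the lower coordinate. Fold enrichment was not among the values used, so chromosome order and then the lower coordinate broke ties instead. Tests that need genes, namely the position of peaks relative to gene starts, the occupancy of 24 gene lists, and genes with a close upstream neighbour, were to be run only with an annotation of WS220. The gene table at hand is of WBcel235, another build, and so these tests were not run and no gene is named. No test over libraries was possible, and no contrast of ChIP with input was computed. The number of peaks, not of libraries, sets the precision of every interval. No p-value here measures the spread between libraries. Alternatives were peaks with the higher scores (50% of each list, or the top 1000), merging of close peaks, other overlap and gap limits, another definition of the centre and covered bases in place of peak numbers. Covered bases were compared by permuting 1 Mb windows (100000 resamples). Permuting such windows for peak numbers, shared peaks alone and peaks up to 5 kb alone were added after seeing the data. So were the tests of broad peaks on the X and of peaks found in a single list, and the values by width and by 1 Mb window.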

Results

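HTZ-1, the Caenorhabditis elegans form of the histone variant H2A.Z, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole wild-type worms of the N2 strain, the standard laboratory strain, at the L3 larval stage. H2A.Z replaces histone H2A in a subset of nucleosomes and is known from many organisms for its place at gene promoters. The series held 2 ChIP libraries, made with a purified polyclonal antibody raised against HTZ-1 in rabbit, and 2 libraries of input DNA, from a mixed male and hermaphrodite population grown at 20 °C. The authors' results were 2 peak lists on the WormBase WS220 build, 1 with 4940 peaks (the larger list) and 1 with 4283 peaks (the smaller list). Each gave a position and a score per peak. Neither list named the libraries behind it, so the lists were treated as separate calls on this experiment and not as replicates. Read depth per library is unknown here, and intervals below cover the counting of peaks only.

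HTZ-1 peaks covered a sizeable part of the worm genome and ranged from narrow sites to regions of many kilobases. The larger list covered 15.3 Mb, or 15.3% of the 100.1 Mb spanned by the 6 nuclear chromosomes, and the smaller list covered 12.1 Mb, or 12.0%. Median peak width was 2280.5 bp in the larger list (quartiles 1624 and 3666.5 bp, bootstrap 95% interval of the median 2237 to 2320 bp). It was 2271 bp in the smaller list (quartiles 1636 and 3543 bp, interval 2230 to 2311 bp). The 50% of peaks with the higher scores had median widths of 3439 bp in the larger list and 2758 bp in the smaller list. The lists parted at the broad end. The larger list held 706 peaks over 5 kb (14.3% of its peaks), 110 of them over 10 kb, and its widest peak measured 27.1 kb. The smaller list held 500 peaks over 5 kb (11.7%), none over 10 kb, and a widest peak of 9.53 kb. The 110 regions over 10 kb made up 1.48 Mb of the larger list. The mitochondrial genome carried 1 peak, in the smaller list, at bases 7911 to 9323 with a score of 66.86, close to the lowest score of that list (50.02).

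The first question was how far the calls placed HTZ-1 at the same sites. Of the 4940 peaks of the larger list, 3763 (76.2%) overlapped a peak of the smaller list by at least 1 bp, and of the 4282 nuclear peaks of the smaller list, 3686 (86.1%) overlapped a peak of the larger list. Random non-overlapping placement of the same peak widths on the same chromosomes gave 25.2% and 27.5% on average. None of 1000 placements reached the observed share in either direction (permutation of peak positions, empirical p = 0.001 for each, one-sided, the smallest value these placements can give). Both lists are calls on the same experiment, and the placements ignore differences in density between regions. An excess over placement was therefore likely beforehand and is no independent evidence for the sites. The lists shared 10.5 Mb of 16.9 Mb covered by either, a Jaccard index of 0.621. Among the 1000 highest-scoring peaks of each list, 43.1% overlapped.

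Agreement changed with the breadth of the region. Between 84.8% (95% Wilson interval 81.6 to 87.4%) and 86.9% (83.0 to 89.96%) of larger-list peaks of 3 to 5 kb were met by the smaller list. Only 38 of 112 peaks of 8 to 10 kb were met (33.9%, 25.8 to 43.1%), and 3 of 110 peaks over 10 kb (2.73%, 0.932 to 7.71%). The median score of the peaks over 10 kb was 2974, against 525.4 for the whole larger list. In the other direction 40 of the 42 smaller-list peaks of 8 to 10 kb were met by the larger list. Agreement was also lower at the narrow end. Of peaks up to 1.5 kb, 70.4% (67.5 to 73.2%) in the larger list and 66.6% (63.3 to 69.8%) in the smaller list were met.

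**Figure D1:**
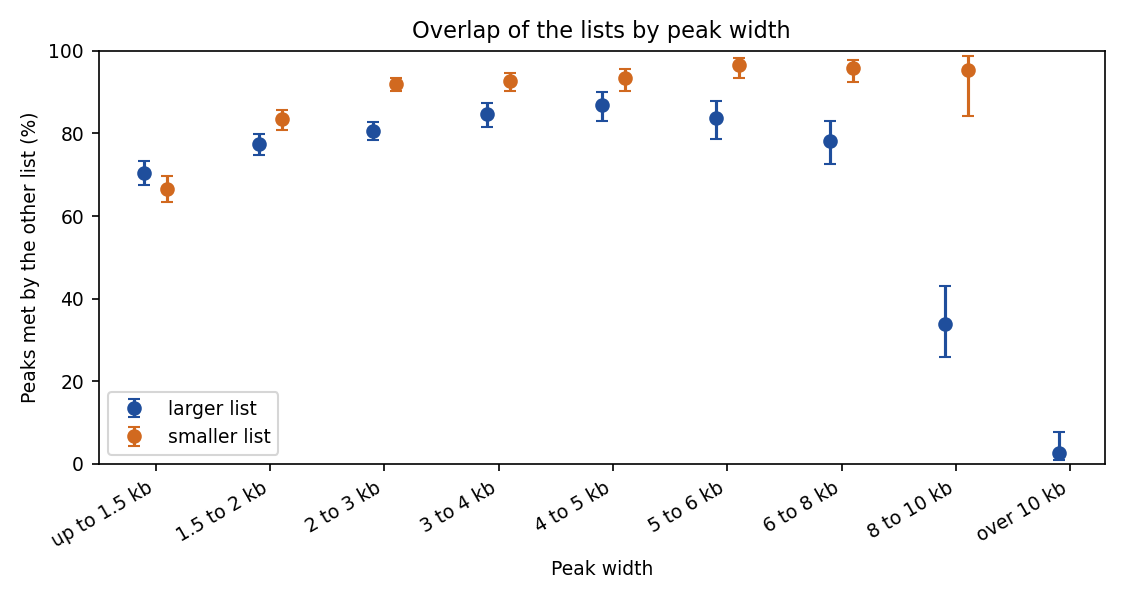
Share of peaks (vertical axis, %) that overlap a peak of the other list by at least 1 bp, by peak width (horizontal axis), for the larger list (blue) and the smaller list (orange), with 95% Wilson intervals. The larger list falls from 86.9% at 4 to 5 kb to 2.73% over 10 kb, while the smaller list has no peak over 10 kb.

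HTZ-1 peaks were sparser on the X chromosome than on the autosomes in both lists. In the larger list the X carried 483 peaks, or 27.3 per Mb, against 54.1 per Mb on the 5 autosomes, a ratio of 0.504 (exact 95% interval 0.458 to 0.554, exact binomial p = 3.62e-55, two-sided). In the smaller list it carried 558 peaks, or 31.5 per Mb, against 45.2 per Mb, a ratio of 0.697 (0.637 to 0.762, exact binomial p = 1.18e-16). Among the 1000 highest-scoring peaks of each list the ratio was 0.149 (0.101 to 0.213) in the larger list and 0.732 (0.607 to 0.879) in the smaller list. Score was tied to width more closely in the larger list (Spearman's rho 0.756) than in the smaller list (0.436). X peaks were narrower, with medians of 1856 against 2337 bp in the larger list and 1843 against 2351.5 bp in the smaller list. A cut by score thus also selects by width. Among the autosomes, chromosomes I and III were the densest, with 71.3 (95% interval 67.1 to 75.7) and 67.6 (63.3 to 72.1) peaks per Mb in the larger list. Chromosome V was the sparsest autosome, with 37.4 (34.8 to 40.1) peaks per Mb. The smaller list gave the same extremes, 55.3 and 55.8 per Mb on I and III and 35.2 per Mb on V. There the X (95% interval 28.9 to 34.2) lay close to V (32.7 to 37.8), and the intervals overlapped. In the larger list the X (24.9 to 29.8) lay below V. Densities are per base of chromosome, and gene density, which differs between chromosomes, was not used here. Neither the share of males in the population nor input coverage was used, so uneven coverage of the X was not tested.

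Broad HTZ-1 regions were rarer still on the X. Peaks over 5 kb made up 17 of 483 X peaks in the larger list (3.52%, 95% Wilson interval 2.21 to 5.56%) and 689 of 4457 autosomal peaks (15.5%, 14.4 to 16.5%; Fisher's exact p = 5.19e-16, two-sided). In the smaller list the shares were 3.05% and 12.97% (Fisher's exact p = 1.25e-14). Chromosomes I and III each carried about 11 such peaks per Mb in the larger list (11.1 and 10.9), against 0.960 per Mb on the X. None of the 110 peaks over 10 kb lay on the X, against 9.78% of all larger-list peaks (exact binomial p = 2.96e-05). As an upper bound, 3 counts in 110 would be a share of 2.73%, which is not a Wilson limit. Chromosome I held 32 of the 110 peaks, III held 30, II held 24, and IV and V held 12 each. X peaks also had the lowest median score of any chromosome in the larger list, 314.3 against 561.0 on autosomes, but not in the smaller list, where the medians were 370.5 and 360.1.

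The lists differed in how strongly the X was depleted. Of the 1177 peaks found in the larger list alone, 29 (2.46%) lay on the X, against 17.4% of the 596 found in the smaller list alone (Fisher's exact p = 5.91e-28, two-sided, odds ratio 8.37). Of all X peaks, 94.0% of those in the larger list (95% Wilson interval 91.5 to 95.8%) and 81.4% of those in the smaller list (77.9 to 84.4%) were met by the other list, against 74.2% (72.9 to 75.5%) and 86.8% (85.7 to 87.8%) of autosomal peaks.

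Along the autosomes, peaks were denser in the centres than on the arms. C. elegans autosomes have gene-dense centres that recombine rarely, and arms richer in repeats. With the centre taken as the middle 33.3% of each autosome, the larger list held 67.2 peaks per Mb in centres and 47.5 on arms, a ratio of 1.42 (1.33 to 1.503, exact binomial p = 1.70e-29, two-sided). All 5 autosomes had ratios above 1 in this list, from 1.23 on I to 1.52 on IV and V, and each passed an exact binomial test with adjusted p of 0.00184 or less over the 12 chromosome tests (Benjamini-Hochberg). The smaller list held 50.3 and 42.6 per Mb, a ratio of 1.18 (1.10 to 1.26, exact binomial p = 1.23e-06). There III, IV and V passed, with ratios of 1.19, 1.33 and 1.34. Chromosomes I (1.01, 0.869 to 1.17) and II (1.08, 0.922 to 1.27) did not. The X gave 1.22 (1.01 to 1.47) and 1.19 (0.996 to 1.42), with adjusted p = 0.0504 and 0.0641 (exact binomial tests). These tests count each peak as independent, although peaks cluster. With 1 Mb windows permuted instead, an alternative chosen after the data were seen, the ratios over autosomes were 1.41 (p = 1e-04) and 1.19 (p = 0.00694, permutation tests, two-sided). Single chromosomes were not tested this way. Windows were exchanged between autosomes as if independent, so these p-values may also be too small. Autosomal peaks in the larger list alone lay in centres more often (53.1% of 1148) than those in the smaller list alone (34.8% of 492; Fisher's exact p = 8.77e-12). The ratio in the smaller list was 1.10 (p = 0.0580) in the 50% of peaks with the higher scores and 0.861 (p = 0.0433) in the top 1000, against 1.47 (p = 1.66e-19) and 1.57 (p = 6.18e-12) in the larger list (exact binomial tests).

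**Figure D2:**
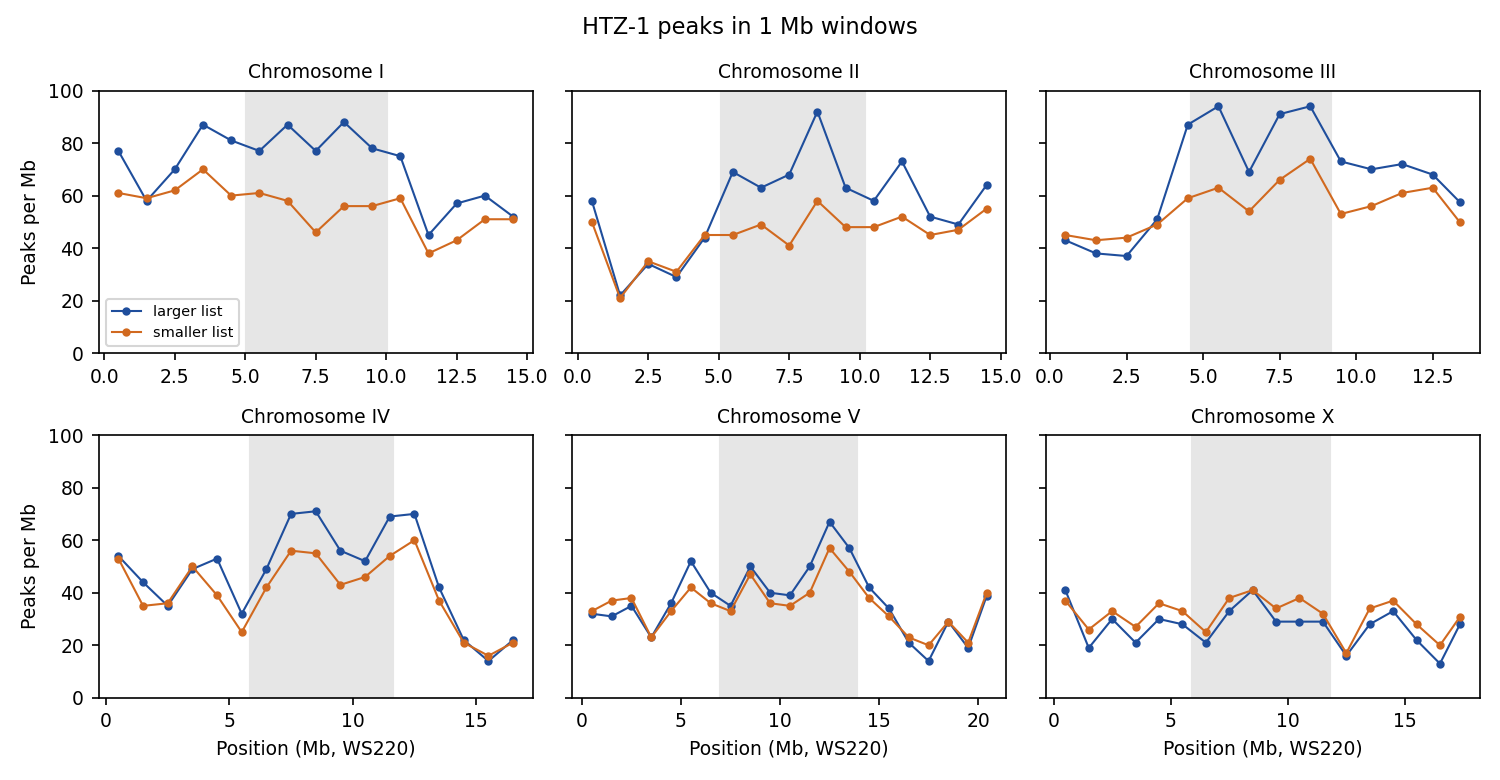
HTZ-1 peaks per Mb (vertical axis) in 1 Mb windows along each chromosome (horizontal axis, position in Mb on WS220) for the larger list (blue) and the smaller list (orange); the grey band is the middle 33.3% of the chromosome and end windows under 0.5 Mb are left out. The highest full window holds 94 peaks in the larger list and 74 in the smaller list, and chromosome X has the lowest density over its whole length, 27.3 and 31.5 per Mb.

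At the scale of 1 Mb the lists ranked regions alike. Across 97 full windows, which are not independent replicates, peaks per Mb correlated between lists with a Spearman rho of 0.940 (bootstrap 95% interval 0.906 to 0.959). A high correlation was likely beforehand for calls on the same experiment. The densest full windows of the larger list were III 8 to 9 Mb and III 5 to 6 Mb, with 94 peaks each, covering 32.1% and 34.4% of the window. The window III 8 to 9 Mb was also the densest of the smaller list, with 74 peaks covering 23.1%. The sparsest was X 16 to 17 Mb in the larger list, with 13 peaks covering 2.64%, and IV 15 to 16 Mb in the smaller list, with 16 peaks covering 3.67%.

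HTZ-1 peaks clustered. In the larger list 47.2% of the 4934 gaps between neighbouring peaks were shorter than 5 kb, against 28.015% on average and at most 29.7% over 1000 random placements (permutation of peak positions, empirical p = 0.001, one-sided, the smallest possible). In the smaller list 30.0% of 4276 gaps were that short, against 22.7% on average and at most 24.5% (permutation of peak positions, empirical p = 0.001). Gaps under 1 kb made up 21.1% in the larger list and 7.02% in the smaller list. The placements spread peaks evenly over each chromosome, so uneven density between regions can by itself give short gaps. Local clustering was not tested apart from it, and no gap test was run on peaks merged within 1 kb. Among the 50% of peaks with the higher scores, gaps under 5 kb made up 28.4% in the larger list, against 14.98% placed (permutation of peak positions, empirical p = 0.001), and 10.7% in the smaller list, against 11.3% placed (empirical p = 0.849).

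Score rose with width over most of the range in the larger list, and only up to about 5 kb in the smaller list. In the smaller list the median score was 111.05 up to 1.5 kb, 680.4 at 4 to 5 kb, 610.7 at 5 to 6 kb, 413.8 at 6 to 8 kb and 135.6 at 8 to 10 kb. In the larger list it was 109.3 up to 1.5 kb, 1910.3 at 4 to 5 kb, 3100 at 6 to 10 kb and 2974 over 10 kb. Across peaks, which are not independent replicates, Spearman's rho of score with width was 0.756 (bootstrap 95% interval 0.742 to 0.770) in the larger list and 0.436 (0.410 to 0.461) in the smaller list. In the 50% of peaks with the higher scores it was 0.570 in the larger list and 0.0755 in the smaller list. Scores of the 3587 pairs in which each peak met a single peak of the other list correlated with a rho of 0.656 (0.633 to 0.677). Some correlation was likely beforehand for calls on the same experiment. Pairs up to 1.5 kb wide had median scores of 125.0 in the larger list and 150.3 in the smaller list. Pairs of 6 to 8 kb had medians of 3100 and 408.3, and pairs of 8 to 10 kb had medians of 3100 and 163.4. The value of exactly 3100 was shared by 569 peaks of the larger list and 81 of the smaller list, and 41 and 10 peaks scored above it. Such a shared value near the top is a limit on any ranking by score, and on the medians of 3100 above. The scale of the score is not stated, so scores of different lists are set side by side and not read as a change.

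**Figure D3:**
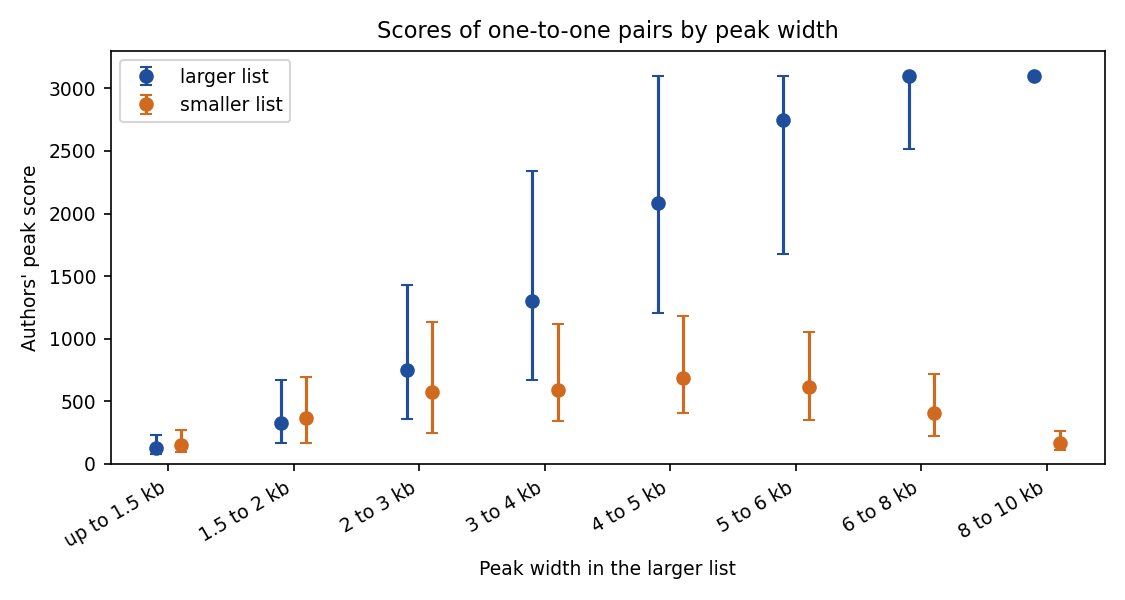
Median of the authors' peak score (vertical axis, no unit stated) in pairs of overlapping peaks, by width of the larger-list peak (horizontal axis); bars are the quartiles, blue is the larger list and orange the smaller list. Larger-list medians climb to 3100 while smaller-list medians peak at 687.3 for 4 to 5 kb and fall to 163.4 for 8 to 10 kb.

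The 10 sites with the highest listed scores in the larger list all lay on autosomes and were 2.45 to 18.05 kb wide. Whether 3100 stands for a limit of the score is not stated, so these sites, and those of the smaller list below, are not shown to be stronger than the 569 and 81 peaks at exactly 3100. The 4 at the top score of 3233 were I 10372134 to 10376217, II 3552414 to 3556024, IV 13238639 to 13244605 and V 14782443 to 14787866, which are 3.61 to 5.97 kb wide. Their counterparts in the smaller list scored 1446, 1554, 599.4 and 453.8. Of the 10, the 2 widest, II 11572446 to 11590491 (18.05 kb) and IV 7471545 to 7488924 (17.4 kb), both with a score of 3225, had no counterpart in the smaller list. The 10 sites with the highest listed scores in the smaller list were 1.79 to 4.13 kb wide. They were led by III 4342345 to 4344382 (score 3223), II 13494029 to 13496371 (3219) and IV 1346106 to 1350030 (3217), whose larger-list counterparts scored 3157, 3100 and 3100. The list included 1 site on the X, at 228992 to 231025 with a score of 3154. The site I 3171111 to 3172905, with a score of 3138, was the only one of these 10 with no peak in the larger list, whereas only 33 of the 81 at exactly 3100 were met there. The broadest regions of the larger list, picked by width after the values were seen, were I 5157079 to 5184154 (27.1 kb, score 3100), IV 360608 to 383851 (23.2 kb, score 297.0) and V 11895955 to 11918324 (22.4 kb, score 81.72). None of the 10 widest overlapped a peak of the smaller list.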

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

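The tests of a local background and of the X difference standardised over width and coverage together were set before their results were seen, and the other tests in this part were chosen after the result was seen. No biological explanation was tested for any of these patterns, since both lists come from worms of the same kind.

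The X chromosome stood out because the lists differed on it: the odds of lying on the X were 8.37 times higher for peaks in the smaller list alone than for peaks in the larger list alone (Fisher's exact p = 5.91e-28). Larger-list peaks on the X were met by the smaller list 19.8 percentage points more often than autosomal peaks (bootstrap 95% interval 17.4 to 22.1). Standardised over peak width and the coverage of the surrounding 10 kb together the difference was 4.63 points (2.75 to 6.53), consistent with a loss of broad and closely neighboured peaks as a source of it, while it was 18.8 points (16.3 to 21.2) over width alone and 10.7 points (8.59 to 12.8) over coverage alone. Breadth by itself is thus no sufficient source, and among peaks up to 5 kb the X to autosome ratios, 0.575 and 0.777, were about as far apart as among all peaks, 0.504 and 0.697. Peaks in the smaller list alone lay on the X (17.4%, 14.6 to 20.7%) more often than its shared peaks (12.3%, 11.3 to 13.4%). An even spread over the length would give about as many (17.7%). They also scored low (median 104.6 against 412.4), so a gain of weak peaks with no preference for the X may add to the difference. Which list is nearer to the true density of HTZ-1 on the X stays open.

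Broad regions of the larger list were nearly absent from the smaller list, which met 2.73% (95% Wilson interval 0.932 to 7.71%) of the peaks over 10 kb (median score 2974). Fewer reads behind the smaller list are argued against as the source of this loss of broad regions by narrow isolated peaks. These were at most 2 kb wide, with no other peak in the surrounding 10 kb. Of 320 such peaks from the lowest quintile of score (median 81.34), 92.5% (89.1 to 94.9%) were met, against 98.7% (96.3 to 99.6%) in the next quintile. Over all larger-list peaks, however, the share met was 58.8%, 73.1%, 81.9%, 86.6% and 80.5% from the lowest to the highest quintile. Fewer reads thus stay open for part of the loss among weak peaks. A limit on width that leaves peaks up to 8 kb called alike is argued against by 3136 pairs with larger-list scores under 3100. In these pairs, up to 8 kb wide, the smaller list's score fell with width at a fixed larger-list score (partial Spearman -0.196, bootstrap interval -0.229 to -0.160). The pairs cannot show whether a width limit exists above 8 kb, and the smaller list's widest peak was 9.53 kb. A candidate explanation is a local background that rises with enriched chromatin around a peak. Among peaks of at most 2 kb, 96.6% of 799 isolated peaks were met. Of 484 with at least 3 kb of other peaks in the surrounding 10 kb, 30.4% were met. The difference was -65.6 points (-69.9 to -61.4) standardised over quintiles of score. The share of crowded peaks met rose, though, from 13.7% of 233 in the lowest quintile to 88.0% of 25 in the fourth. These narrow peaks scored low (medians 177.7 isolated and 138.2 crowded). The test was not run on broad peaks, so it does not show that such a background removes broad regions of high score. Merging of crowded peaks before a width limit stays open for part of the loss, since 324 of the 1177 unmatched peaks lay in gaps too short for the smaller list's widest peak and the rest did not, and so does the use of different libraries, controls or settings.

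Many of the smaller list's peaks with the highest listed scores were missing from the larger list. Of its 91 peaks scoring at or above 3100, 49 had no counterpart (53.8%, 95% Wilson interval 43.7 to 63.7%), against 2.92% (1.99 to 4.28%) in the quintile below the highest. The 49 had a median width of 3443 bp, 13 of them lay on the X, and all but 1 scored exactly 3100, where 33 of 81 peaks were met against 9 of the 10 above it. All 5 peaks at the first bases of chromosomes were absent from the larger list too, as they would be if sequence over-represented in any library were removed by a comparison with input. This explanation cannot be told apart from others for the 49 peaks without the coverage of the input libraries, which was not analysed here.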

How the results depend on the processing

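No paired analysis was possible because the peak lists hold no values per library, so no replicate number can serve as a block and no library can be left out. Permuting 1 Mb windows of peak numbers, shared peaks alone and peaks up to 5 kb alone were chosen after seeing the data, while permuting windows of covered bases was planned. Of 55 alternatives, 44 kept the direction and the side of the threshold or, with no test, stayed within 1.5 times the number of peaks or within the 95% interval. X to autosome ratios stayed below 1 and past the threshold in every alternative run, from 0.149 (top 1000) to 0.638 (shared peaks) in the larger list and from 0.520 (covered bases) to 0.777 (peaks up to 5 kb) in the smaller list; peaks up to 5 kb gave 0.575 in the larger list. With 1 Mb windows permuted in place of single peaks, the ratios were 0.504 (p = 2e-05, the smallest possible) and 0.696 (p = 6e-05, permutation tests, two-sided). All X windows lie on a single chromosome, and windows were exchanged between chromosomes as if independent, so these p-values too may be too small. Centre to arm ratios stayed above 1 in every alternative run on the larger list (1.19 to 1.57). In the smaller list the ratio was 1.10 (p = 0.0580) in the 50% with the higher scores and reversed to 0.861 (p = 0.0433) in the top 1000 (exact binomial tests), and was 1.12 to 1.21 in the others; the cause was not tested. Keeping the 50% with the higher scores left 2470 and 2141 peaks by construction, raised median widths to 3439 and 2758 bp, lowered the correlation of score with width to 0.570 and 0.0755, and reversed the excess of gaps under 5 kb in the smaller list, to 10.7% against 11.3% placed; the cause was not tested. Merging within 200 bp moved the larger list's median width to 2333 bp, and leaving out the widest 5% moved the smaller list's correlation to 0.488. Overlap shares stayed above random placement in every alternative run, down to 43.1% for the top 1000 of each list, which was likely beforehand for calls on the same experiment. Alternatives that need genes, a summit or fold enrichment were not run. Reads per library are unknown, so what depth limits cannot be stated.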

Other observations

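The values and tests in this part were chosen after the data were seen.

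Long stretches without HTZ-1 peaks lay mostly on chromosomes IV, V and X. Gaps over 100 kb numbered 121 in the larger list, 2.45% of its gaps against 0.857% on average and at most 1.20% over 1000 random placements (permutation of peak positions, empirical p = 0.001, one-sided, the smallest possible). The smaller list had 110, or 2.57% against 1.09% and at most 1.54% (permutation of peak positions, empirical p = 0.001). These placements too ignore differences in density between regions, and they treat every base as open to a peak. Input coverage of these stretches was not analysed, so a lack of mapped reads there was not tested. Of the 121, 39 lay on X, 36 on V, 21 on IV, 14 on II, 7 on I and 4 on III. These counts are not per length, and X, V and IV are also the longest chromosomes, with 17.7, 20.9 and 17.5 Mb of the 100.1 Mb spanned. At least 50% of the length of 95 of the 121 fell inside a gap over 100 kb of the smaller list. The longest gap was nearly identical in both lists, IV 15984956 to 16388578 (403.6 kb) in the larger and IV 15985006 to 16388563 in the smaller. The next longest of the larger list were shorter in the smaller list. On the X, 3804208 to 4189269 (385.1 kb) was split there into gaps of 221.4 and 157.6 kb, and on V, 17156442 to 17513948 (357.5 kb) left 1 gap over 100 kb, of 151.8 kb.

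The right ends of chromosomes IV and V were sparse. The last 20% of IV by length, from 13.98 Mb on, held 76 peaks in the larger list, or 21.8 per Mb against 53.3 per Mb on the rest of the chromosome (ratio 0.408, exact 95% interval 0.318 to 0.517, exact binomial p = 8.15e-17, two-sided), and 75 peaks in the smaller list, or 21.5 against 45.1 per Mb (ratio 0.476, 0.370 to 0.606, exact binomial p = 3.21e-11). The last 20% of V held 24.0 per Mb against 40.7 on the rest in the larger list (ratio 0.589, 0.473 to 0.728, exact binomial p = 1.83e-07) and 26.1 against 37.5 in the smaller list (ratio 0.698, 0.564 to 0.856, exact binomial p = 3.72e-04). On I, II, III and X the ratios ran from 0.757 to 0.977 in the larger list and from 0.842 to 1.08 in the smaller list. Gene positions on WS220 and input coverage were not used here. The regions were singled out after their values were seen, and peaks cluster, so these p-values are too small.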
